A study of Mus musculus with 4 samples.

How the data were processed

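Gene expression was measured in Thy1+ LSK cells sorted from mouse bone marrow, a fraction that is lineage-negative, carries Sca-1 and Kit, and is enriched for haematopoietic stem cells. The arrays came in 2 groups of 2. One group was wild type for Nol3 (Nol3+/+). The other lacked both copies and is marked by the labels as MPN (Nol3-/- MPN), taken here as myeloproliferative neoplasm. The series title can also be read as giving MPN to both genotypes. The sample labels, which give it to Nol3-/- only, were followed, so whether disease differs between the groups along with genotype rests on them. The labels give the C57BL/6 background and an age between 11 and 18 months for both groups, and they do not give the sex of the animals. Nothing in the labels says whether each array held the RNA of 1 animal or of several. The p-values of single genes therefore measure the spread between these arrays only.

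Per the labels' protocols, RNA was extracted with a column kit for small samples, amplified by single-primer isothermal amplification and labelled with biotin for whole-transcript Affymetrix arrays. Per the submitters' processing notes, Affymetrix Expression Console and Transcriptome Analysis Console were used. Their versions, the background correction and the normalization method are not given in the sources used here. The authors deposited 1 table of normalized values, with 41345 rows and a column for each of the 4 arrays. The deposited values were treated as log2 signals per transcript cluster. That scale was taken from the values themselves, which run from 2.84 to 13.5 with array medians of 5.38 and 5.37 in Nol3+/+ and 5.35 and 5.39 in Nol3-/- MPN, and the base of the logarithm is not stated, so every fold change rests on base 2. The array medians lie close together and the values are not centred per row. Detection p-values and scanner intensities were not used here, so a low signal cannot be separated from background, and the number of arrays limits the precision.

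Genes were named through the platform annotation, which lists 25335 of the rows. Of all rows, 23521 had 1 gene symbol, 1814 had several and 16010 had none, and only the first kind was given a gene name. Those rows stood for 22180 genes. For the 1082 genes with several rows, the row with the highest mean over all arrays was used. Of the gene identifiers, 21994 were found in a RefSeq table of assembly GRCm38.p6 and 186 were not. No symbol needed an update. That table gave chromosome, gene type and gene order, and its coordinates served only to order genes and to find the host gene of Snord92. Genes whose mean over all arrays lay under the 25th percentile of the gene rows, a log2 signal of 4.835, were left out as dim. This left 16635 genes for testing and removed 5545. No genome sequence was used.

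The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend on mean signal), with 2 residual and 3.19 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A looser descriptive count took genes at least 2-fold different at an unadjusted p under 0.05. SE denotes limma's standard error of the log2 difference, SD the spread of the 2 arrays of a group, and intervals are 95% intervals. Of 30 gene lists, 29 had at least 5 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists. The list of mitochondrially encoded genes had 0 matched rows. Each list was also tested with an estimated correlation, for which camera takes its degrees of freedom from the residual ones, and with fry, which asks whether members move on balance one way (directional) or in either direction (mixed). The share of genes at an unadjusted p under 0.05 among the 50 tested genes on each side of Nol3 was compared with that of other genes by a two-sided Fisher's exact test. Camera at the preset correlation and Fisher's exact test take genes, not arrays, as their units. Their p-values therefore do not measure the spread between arrays.

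The tests, lists and alternatives were set before the data were examined, except where the text says otherwise. Named genes followed a fixed rule. It took Nol3, then the 12 higher and the 12 lower genes with the smallest limma p among those that differed at least 2-fold with no overlap between the groups, past the adjusted threshold or not. Predicted and clone-named genes, microRNA and small nucleolar RNA genes, chemosensory receptors, and immunoglobulin and T cell receptor segments were left out of these 24 places. From each list the 3 members with the smallest p and all measured sex-linked genes were added, and further list members serve as examples of their group. Of 108 genes named by the rule, 11 had several rows, and those of Hspb1 disagreed in sign. The alternatives covered the replicate number as a block, each array left out in turn, other variance models, array weights, other normalizations, other limits for dim genes, the mean of a gene's rows, other thresholds and other set tests. Analyses without X- and Y-linked genes and of protein-coding genes only were added after seeing the data.

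The fit was tested on simulated data with 16635 genes and 2 arrays per group. At a log2 change of 2, 66 of 100 changed genes passed the adjusted threshold and 96 of 100 met the looser criterion. At a log2 change of 1, 2 of 100 passed the adjusted threshold and 54 of 100 met the looser one. Of 16435 unchanged genes, 1 passed the adjusted threshold and 122 met the looser criterion. A simulated list shifted by 0.25 log2 units was called with a camera adjusted p of 5.7e-07, and 0 of the 28 other lists were called. Genes were simulated independently of each other and with the same spread in both groups. The simulation therefore cannot tell how often lists of correlated genes are called falsely. No 2 arrays held identical values.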

Results

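Whole-transcript arrays profiled Thy1+ LSK bone marrow cells of 2 Nol3+/+ and 2 Nol3-/- MPN samples from mice aged 11 to 18 months. The comparison asks how gene expression in this stem cell-enriched fraction differs between mice that lack Nol3 and carry the disease label and mice with intact Nol3. The 4 arrays had similar signal distributions, with medians between 5.35 and 5.39 log2 units. Across the tested genes the 2 Nol3-/- MPN arrays correlated at r = 0.949 and the 2 Nol3+/+ arrays at r = 0.911, a comparison across genes, which are not independent replicates. Nol3+/+ replicate 1 stood apart from the other arrays. It correlated with the Nol3-/- MPN arrays at r = 0.899 and 0.908, whereas Nol3+/+ replicate 2 correlated with them at r = 0.929 and 0.945. The sort genes were Kit, at 8.09 ± 0.02 in Nol3+/+ and 7.88 ± 0.70 in Nol3-/- MPN, and Thy1, at 4.88 ± 0.19 and 4.94 ± 0.42 (mean log2 signal ± SD, n = 2 per group), the latter close to the limit for dim genes of 4.835.

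Nol3 encodes an inhibitor of apoptosis also known as ARC, and its signal did not differ between the genotypes. It read 5.31 and 5.52 in the Nol3+/+ arrays and 5.38 and 5.50 in the Nol3-/- MPN arrays. The log2 difference was 0.02 with an SE of 0.14 and an interval from -0.34 to 0.38 (limma adjusted p = 0.995). The row lay at percentile 50.3 of all gene rows and at percentile 72.3 among 1105 olfactory receptor genes, whose median was 4.69. Where the deletion lies relative to the probes is not given in the labels, so this row does not check the genotype labels. Genes next to Nol3 on chromosome 8 showed no excess of differences. Of the 100 nearest tested genes, 3 (3%) reached an unadjusted p under 0.05 against 5.82% of 16534 other genes, an odds ratio of 0.50 with an interval from 0.10 to 1.51 (two-sided Fisher's exact p = 0.287).

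The clearest difference between the groups was in sex-linked genes. Xist, the non-coding RNA that coats the inactive X chromosome of female cells, rose from 5.36 ± 0.11 in Nol3+/+ to 10.8 ± 0.13 in Nol3-/- MPN, a log2 difference of 5.43 with an SE of 0.22 (limma adjusted p = 0.0234). The Y-linked gene Gm20815 fell by 4.48 log2 units, from 8.69 ± 0.25 to 4.21 ± 0.11 (limma adjusted p = 0.0234). Of 13 tested Y-linked genes, 11 lay lower in both Nol3-/- MPN arrays than in both Nol3+/+ arrays, and the median log2 difference of the 13 was -2.32. Single Y-linked genes other than Gm20815 missed the adjusted threshold. The log2 difference was -2.74 for Eif2s3y, -1.50 for Uty, -1.19 for Kdm5d, -4.21 for Sly and -2.78 for Srsy, with limma adjusted p-values of 0.198, 0.477, 0.841, 0.273 and 0.273. In Nol3-/- MPN the mean signals of Gm20815, Eif2s3y, Uty, Kdm5d and Sly were 4.21, 4.11, 4.60, 4.29 and 3.97, below the limit for dim genes, so these differences are of deposited signals and do not measure a change in transcript amount. Gm20815, Sly and Srsy belong to families with near-identical copies, so their rows may not separate single genes. Kdm6a, an X-linked histone demethylase that escapes X inactivation, differed by 1.42 (limma adjusted p = 0.692), Ddx3x by 0.00 and Kdm5c by -0.01. Of 612 X-linked genes without Xist, 30.2% lay higher and 10.5% lower in both Nol3-/- MPN arrays, against 19.3% and 16.02% of autosomal genes. The Nol3+/+ arrays thus carried Y-linked signal and the Nol3-/- MPN arrays carried Xist signal, so genotype, the disease label and this difference in sex-linked signal follow the same division of the 4 arrays.

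**Figure D1:**
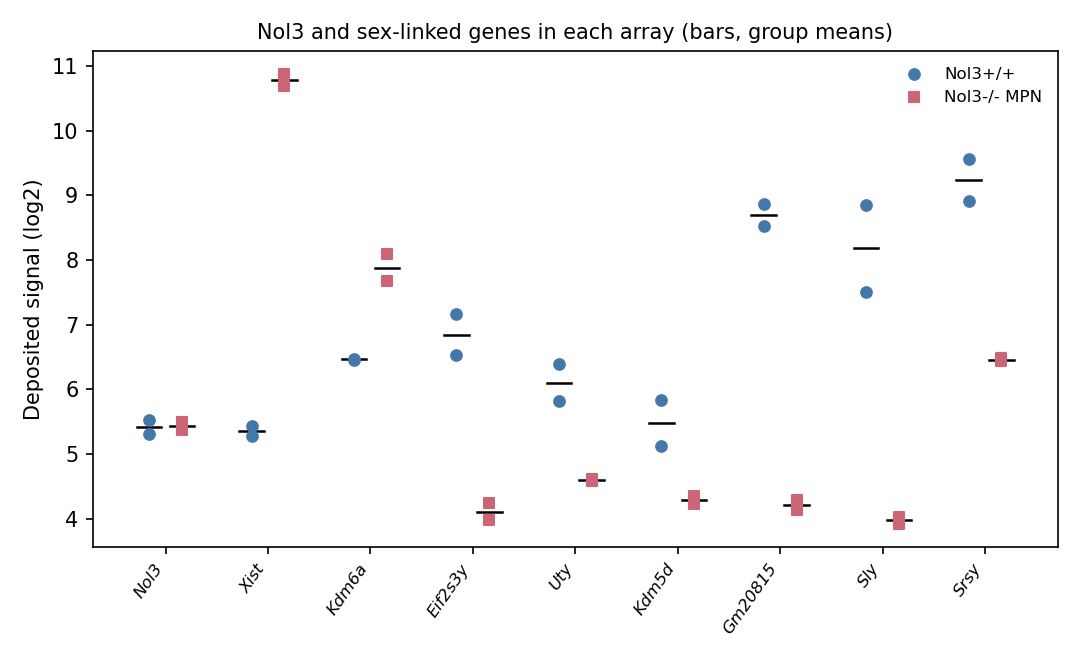
Deposited log2 signal (vertical axis) of Nol3 and 8 sex-linked genes in each array, with Nol3+/+ arrays as circles, Nol3-/- MPN arrays as squares and bars at the group means. Nol3 overlaps between the groups, Xist lies near 10.8 only in Nol3-/- MPN, and the 6 Y-linked genes lie lower in both Nol3-/- MPN arrays.

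In all, 4 of 16635 genes passed the adjusted threshold, 2 higher and 2 lower in Nol3-/- MPN. Besides Xist and Gm20815 these were a pair of autosomal non-coding RNA genes, named here because the count is small. Neither passed when X- and Y-linked genes were left out, where limma called 0 genes (adjusted p = 0.0648 for both) and 147 genes differed at least 2-fold at an unadjusted p under 0.05. Over all genes, 0 passed with the replicate number as a block and 0 in the ordinary test without moderated variance. Snord92, a small nucleolar RNA gene on chromosome 17, rose by 4.12 log2 units with an SE of 0.22, from 3.96 and 3.81 in the Nol3+/+ arrays to 8.26 and 7.74 in the Nol3-/- MPN arrays (limma adjusted p = 0.0329). Its Nol3+/+ signals also lay below the limit for dim genes and cannot be separated from background, so the difference is of deposited signals here too. 4930539J05Rik, a long non-coding RNA gene on chromosome 3, fell by 3.96 log2 units, from 9.19 ± 0.22 to 5.23 ± 0.08 (limma adjusted p = 0.0351). Small RNA rows were variable between replicates, and 23.7% of 278 small RNA genes differed at least 2-fold between the arrays of 1 group, against 5.36% of other genes. None of the 4 calls held without Nol3-/- MPN replicate 1 or without Nol3-/- MPN replicate 2, where limma called 0 genes by adjusted p. Without Nol3+/+ replicate 1 it called 18 genes, 2 higher and 16 lower, and without Nol3+/+ replicate 2 it called 39, 3 higher and 36 lower. An unadjusted p under 0.05 was reached by 965 genes, against 831.75 expected by chance. The looser criterion of a 2-fold difference at that p took 169 genes, 105 higher and 64 lower, of which 145 were autosomal, 15 X-linked and 9 Y-linked. Chemosensory receptor genes made up 25 of the 169, against 631 of the 16635 genes tested. The criterion was also met by 122 of 16435 unchanged genes in the simulated data. Other splits of these arrays put the group difference within each side, where it widens the spread, so they give no baseline free of it. In such splits the criterion took 112 genes with replicate 1 of both groups against replicate 2 of both. It took 65 with Nol3+/+ replicate 1 and Nol3-/- MPN replicate 2 against the other arrays. Its balance turned without Nol3+/+ replicate 1, with 252 genes, 106 higher and 146 lower. It took 538 genes, 341 higher and 197 lower, without Nol3+/+ replicate 2, 194, 138 higher and 56 lower, without Nol3-/- MPN replicate 1, and 310, 225 higher and 85 lower, without Nol3-/- MPN replicate 2. The arrays of the groups did not overlap for 5909 genes, against 5545 expected by chance.

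Among the autosomal genes named by the fixed rule with higher values in Nol3-/- MPN, S100a6, a calcium-binding protein gene, read 6.05 ± 0.05 against 8.23 ± 0.46 (log2 difference 2.18, SE 0.28). Casp4, which encodes the caspase that senses cytosolic lipopolysaccharide, read 4.89 ± 0.05 against 6.15 ± 0.29. Ndufa3, a subunit of respiratory complex I, differed by 1.60 and Fkbp2, a peptidyl-prolyl isomerase of the endoplasmic reticulum, by 1.47. The ribosomal protein genes Rpsa and Rps10 differed by 1.31 and 1.06. Eloc (elongin C), Clnk (an adaptor of immune receptor signalling), Snrpb2 (a U2 spliceosomal protein) and Ddb1 (an adaptor of the CUL4 ubiquitin ligase) differed by 1.24, 1.25, 1.11 and 1.05. Among those with lower values, Irf8, a transcription factor of monocyte and dendritic cell development, read 7.86 ± 0.19 in Nol3+/+ and 6.03 ± 0.54 in Nol3-/- MPN (log2 difference -1.83, SE 0.32). The circadian transcription factor gene Clock differed by -1.27, the cytokine gene Il18 by -1.06 and Gch1, the first enzyme of tetrahydrobiopterin synthesis, by -1.03. Smok4a, listed as a transcribed pseudogene, differed by -1.21. Dnajb14, a co-chaperone gene, differed by -2.76, but its Nol3+/+ arrays were spread by an SD of 1.35. Its Nol3-/- MPN mean of 4.82 lay below the limit for dim genes, so this too is a difference of deposited signals. Astx5, an X-linked gene, differed by -2.07. None of these genes passed the threshold over all genes, with limma adjusted p-values between 0.311 (Astx5) and 0.841 (Il18, Dnajb14 and Smok4a). In simulated data of this size 2 of 100 genes changed by 1 log2 unit were called, and 66 of 100 changed by 2 log2 units.

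**Figure D2:**
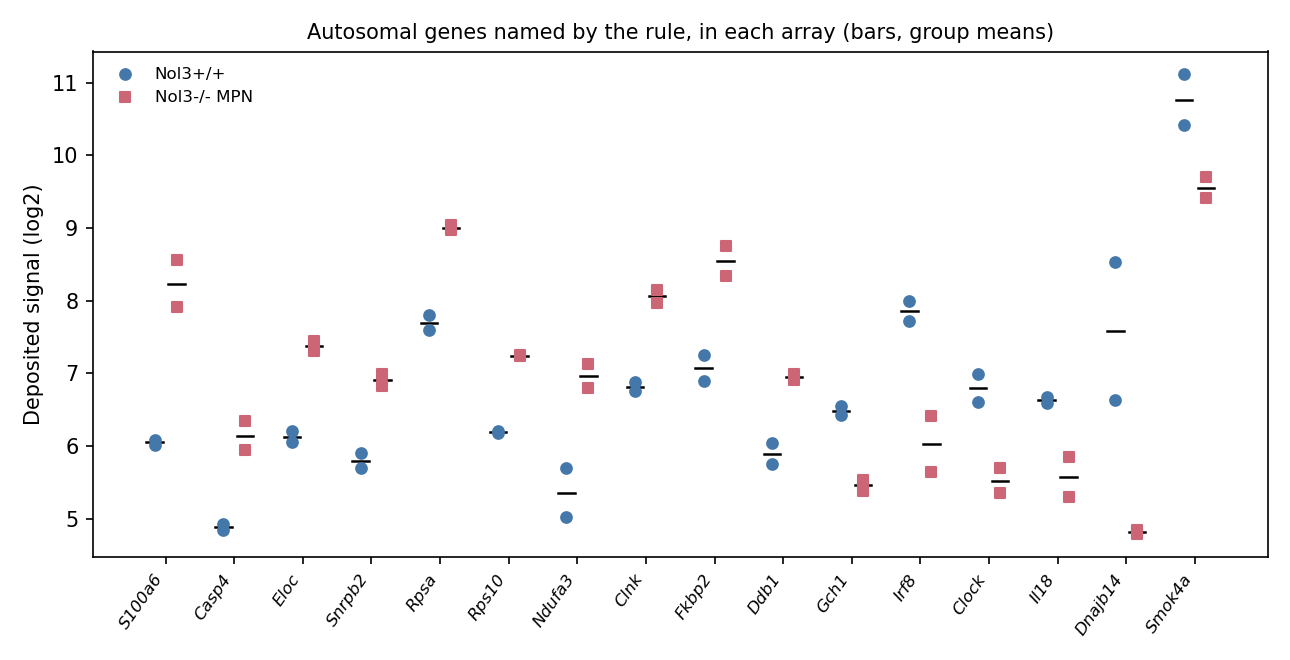
Deposited log2 signal (vertical axis) of the autosomal genes named by the fixed rule in each array, with Nol3+/+ arrays as circles, Nol3-/- MPN arrays as squares and bars at the group means. The groups do not overlap for any gene shown, a condition of the rule, and Dnajb14 has the widest spread between replicates, with an SD of 1.35 in Nol3+/+.

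Of 29 gene lists tested, 4 passed the camera threshold at the preset correlation, all with higher values in Nol3-/- MPN. Each call was lost with an estimated correlation (camera adjusted p = 0.577 for each list), where camera had only 2 residual degrees of freedom. The estimates lay between -0.02 and 0.03, on both sides of the preset 0.01. With 2 residual degrees of freedom they are too imprecise to tell how far members are correlated, so they do not check the preset value. Even the smallest unadjusted camera p of these 4 lists was then 0.0463, for the ribosomal list. Fry called 0 of the 29 lists directionally and 1, the sex-linked list, in either direction. Oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, had 39 of 51 measured members higher and 12 lower, a median log2 difference of 0.25 (camera adjusted p = 0.0014). Of these, 7 members were higher and 1 lower at an unadjusted p under 0.05, and Cox4i1, Sdhc, Atp5g2 and Ndufa9 differed by 1.73, 0.98, 0.97 and 0.83. The median signal of this list was 7.10 and 7.63 in the Nol3+/+ arrays and 7.51 and 7.99 in the Nol3-/- MPN arrays. These medians overlap between the groups, with Nol3+/+ replicate 2 above Nol3-/- MPN replicate 1. Ribosomal protein genes had 37 of 49 members higher, with a median of 0.19 (camera adjusted p = 0.0033), and the members with the smallest p were Rps10 at 1.06, Rps15 at -0.68 and Rps25 at 0.93. Many ribosomal protein genes have processed pseudogenes, so their rows are uncertain. Interferon-stimulated genes had 29 of 37 members higher, with a median of 0.22 (camera adjusted p = 0.0054). Their leading members were Irgm2, an interferon-inducible GTPase gene, at 1.42, Parp9 at 0.70 and Gbp3 at 0.59. Mitotic cell cycle genes had 32 of 41 members higher, with a median of 0.10 (camera adjusted p = 0.0152), led by the kinesin gene Kif20b at 0.84, Cks2 at 0.77 and the spindle checkpoint gene Bub1b at 0.65. That median lay at percentile 84.97 of random lists of the same size and brightness, against 99.6 or more for the other lists called. In each of these lists 0 members passed the threshold over all genes and 0 did when adjusted over the list alone. At the preset correlation the oxidative phosphorylation list was called whichever array was left out, with a median of 0.13 without Nol3-/- MPN replicate 2 (camera adjusted p = 0.0476) and 0.35 without Nol3-/- MPN replicate 1. The median of the interferon list was 0.13 without Nol3+/+ replicate 1 and 0.14 without Nol3-/- MPN replicate 1, and that of the mitotic list 0.18 without Nol3+/+ replicate 1 and 0.06 without Nol3+/+ replicate 2. Without Nol3-/- MPN replicate 1 the camera adjusted p of the ribosomal, interferon and mitotic lists was 0.118, 0.208 and 0.208, although the ribosomal and mitotic medians were then higher, at 0.23 and 0.14. Without Nol3+/+ replicate 1 that of the interferon list was 0.0557, and without Nol3+/+ replicate 2 that of the mitotic list was 0.190.

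**Figure D3:**
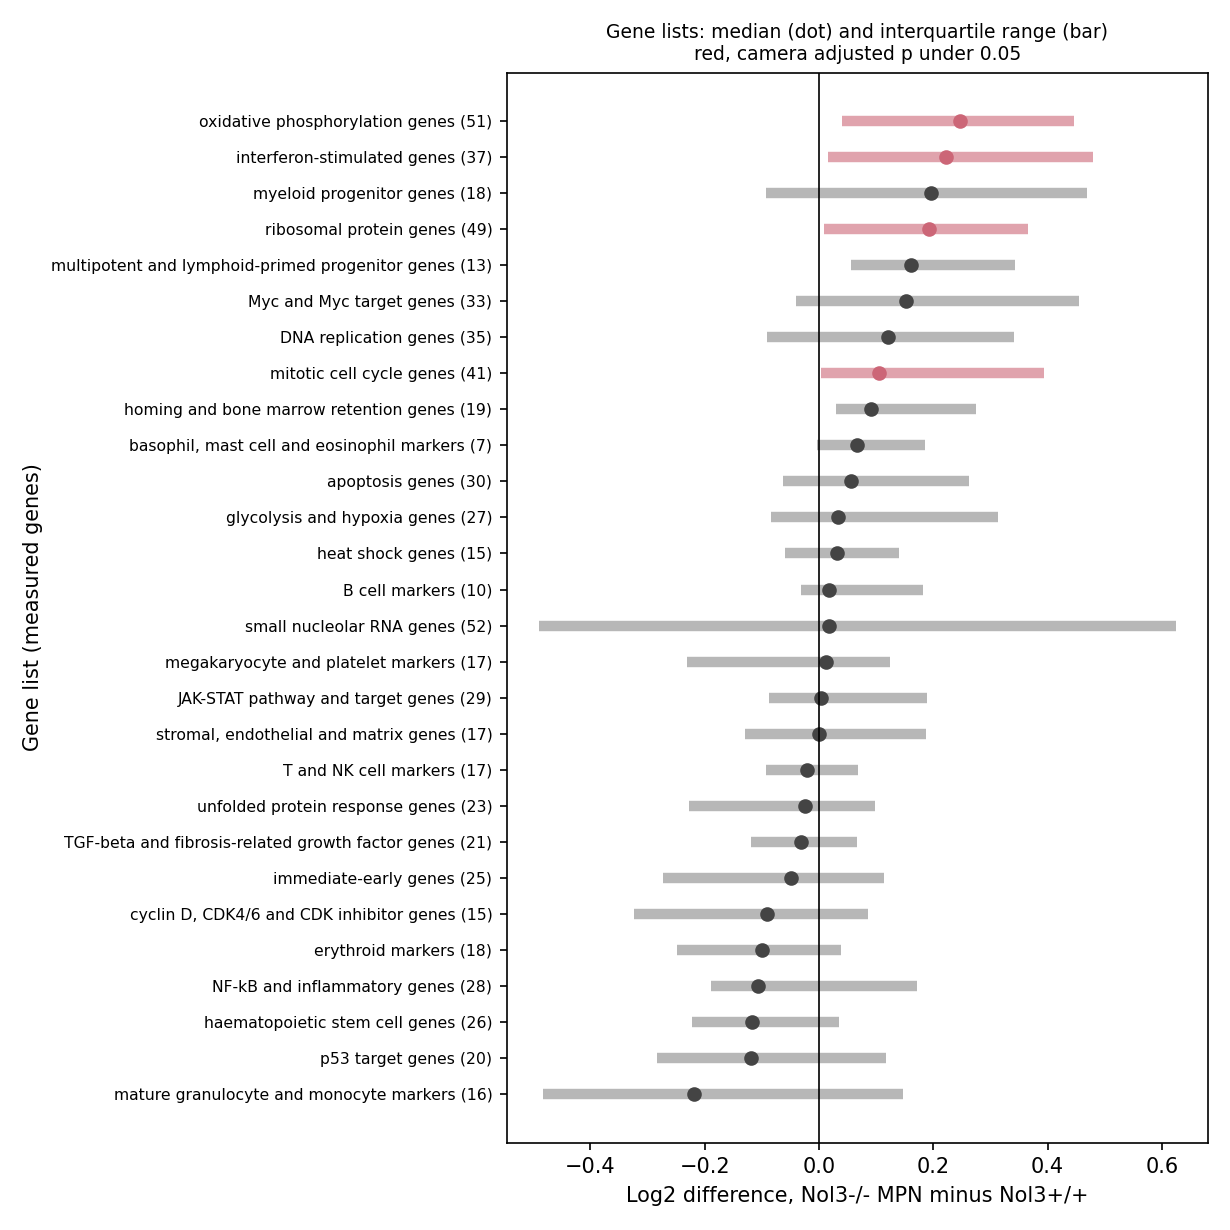
Log2 difference between Nol3-/- MPN and Nol3+/+ (horizontal axis) for each gene list with its number of measured genes, drawn as the median (dot) and interquartile range (bar) over members, without the sex-linked list. The 4 lists past the camera threshold are red, with medians of 0.25, 0.22, 0.19 and 0.10, and the bars of the other lists cross 0, except those of the multipotent progenitor and homing lists.

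None of the lists of blood cell states passed the threshold. Haematopoietic stem cell genes had 18 of 26 members lower and a median of -0.12 (camera adjusted p = 0.106), led by the transcription factor gene Hlf at -0.83, with Erg at 0.60 and Mycn at -0.45. Multipotent and lymphoid-primed progenitor genes had 11 of 13 members higher and a median of 0.16 (camera adjusted p = 0.106), with Cd48 at 1.41, Ccr9 at 0.41 and Satb1 at 0.34. At the preset correlation that list was called without Nol3+/+ replicate 2 (median 0.32, camera adjusted p = 0.0301) and without Nol3-/- MPN replicate 2 (median 0.37, 0.0249), against values up to 0.756 over its alternatives. Over all arrays its adjusted p was 0.577 with an estimated correlation. Myeloid progenitor genes had a median of 0.20 (0.166). Within them Irf8 passed the threshold when adjusted over the list alone, with an adjusted p of 0.0345, while Prtn3 and Nkg7, genes of granule proteins, differed by 0.50 and 0.86. Mature granulocyte and monocyte markers had a median of -0.22 (camera adjusted p = 0.110), with the calprotectin genes S100a8 and S100a9 at -0.86 and -0.83 and Adgre1 at 0.37. At the preset correlation this list was called lower without Nol3+/+ replicate 1 (median -0.30, camera adjusted p = 5.6e-04), whereas without Nol3+/+ replicate 2 its median was 0.03 (0.872, the highest over its alternatives). Over all arrays its adjusted p was 0.577 with an estimated correlation. Erythroid markers had a median of -0.10 (0.166), with Tfrc at 0.66, Car2 at -0.42 and Rhd at -0.35. The medians of megakaryocyte and platelet, B cell, T and NK cell, basophil, mast cell and eosinophil, and stromal markers were 0.01, 0.02, -0.02, 0.07 and 0.00, with camera adjusted p-values of 0.684, 0.684, 0.772, 0.796 and 0.701. The genes with the smallest p in them were Pf4 at 0.59, Mmrn1 at -0.83, Itgb3 at -0.30, Cd79b at 0.50, H2-Aa at -0.89, Cd79a at 0.19, Cd2 at 0.18, Cd8a at 0.13, Ncr1 at -0.19, Prg2 at -0.82, Ms4a2 at 0.28, Cpa3 at 0.70, Col3a1 at -0.35, Sparc at 0.31 and Pdgfrb at -0.20.

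The lists for growth, signalling and survival also missed the threshold. Myc and Myc target genes had 21 of 33 members higher and a median of 0.15 (camera adjusted p = 0.106), with Myc at 0.54, Nop16 at 0.49 and Rrp9 at -0.36, and at the preset correlation this list passed after quantile normalization (0.0428) and with the stricter limit for dim genes (0.0357), against values up to 0.395 over its other alternatives. Its adjusted p was 0.577 with an estimated correlation. DNA replication genes had a median of 0.12 (0.161), with the replicative helicase genes Gins1 at 1.06 and Mcm6 at 0.81 and with Rpa2 at -0.49. In the list of D cyclins, CDK4/6 and CDK inhibitors (median -0.09, camera adjusted p = 0.387), Cdk6 read 8.09 ± 0.42 and 9.03 ± 0.13, while Cdkn2a and Cdkn1a differed by -0.30 and -0.55. JAK-STAT pathway genes, central to human myeloproliferative neoplasms, had a median of 0.00 (0.701), with Cbl at 0.67, the phosphatase gene Ptpn11 at 0.56 and Lif at -0.41. Apoptosis genes, chosen for the known role of Nol3, had a median of 0.06 (0.323), with Fas at 0.32, Htra2 at 0.79 and Casp6 at 0.37. The p53 target genes had a median of -0.12 (0.323), with Ei24 at 1.05 and Aen at -0.28. Immediate-early genes, which respond to cell handling as well as to signals, had a median of -0.05 (0.106), with Nr4a2 at -0.60, Fos at -0.51 and Egr1 at -0.38. The median was -0.11 for NF-kB and inflammatory genes, led by Ccl4 at -0.55, -0.03 for TGF-beta and fibrosis-related genes, led by Smad2 at 0.73, 0.03 for glycolysis and hypoxia genes, led by Egln3 at 0.69, 0.03 for heat shock genes, led by Chordc1 at -0.34, -0.03 for unfolded protein response genes, led by Dnajc3 at 0.59, and 0.09 for homing genes, led by the integrin gene Itgb2 at 0.53. The camera adjusted p-values of these lists were, in the same order, 0.323, 0.684, 0.480, 0.951, 0.560 and 0.166. Small nucleolar RNA genes had 26 of 52 members higher and a median of 0.02 (0.701). When adjusted over the list alone, 3 of them were higher, namely Snord92, Snord73a at 3.22 and Snord49b at 0.95. The sex-linked list had a median of -0.01 (0.517), and 2 members were higher and 3 lower when adjusted over the list alone. For the megakaryocyte, B cell, stromal, TGF-beta and sex-linked lists the median, the mean and the direction of the test did not share a sign.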

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

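The tests of sex, of loss of the Y chromosome, of brightness and of the host transcript as the whole cause were chosen after the results they bear on had been seen.

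Signal differing between the groups also appeared in rows the comparisons left out because they do not name a single gene. Among 9787 tested rows with no gene name, 15 passed the limma threshold of 0.05 after adjustment, 5 higher and 10 lower in Nol3-/- MPN, the largest by 5.27 log2 units. Among 1502 tested rows with several gene names, 76 passed, all lower in Nol3-/- MPN and all annotated to Y-linked genes, the largest by 7.22 log2 units. Both kinds of row were fitted and adjusted together, apart from the named genes. The many Y-linked rows that passed loosen the unadjusted p needed by the others. The 15 rows with no gene name thus met a less strict limit than the called genes.

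The sex-linked pattern (Xist higher, Y-linked genes lower) has a loss of the Y chromosome from the Nol3-/- MPN cells and a difference in the sex of the animals as its main explanations. Loss of the Y chromosome alone would leave Xist where it was, and the lower bound of the Xist difference, 4.86 log2 units, excludes it as the whole cause. Animals of different sex in the groups would lower most Y-linked genes, and 11 of 13 lay lower in both Nol3-/- MPN arrays. These genes are part of the pattern itself, so the count is no separate test. Xist read 5.43 and 5.28 in the Nol3+/+ arrays and 10.9 and 10.7 in the Nol3-/- MPN arrays. Together with the Y-linked signal, these values argue against animals of the same sex in both groups. The labels do not give the sex, so it could not be checked against them. An exchange of whole groups between labels was not tested because the Nol3 row does not check the genotype.

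The 4 gene lists with higher values in Nol3-/- MPN were set against the array that stands apart, brightness, sex and chance. Each of these lists was lost with an estimated correlation, where camera had 2 residual degrees of freedom (camera adjusted p = 0.577). Without Nol3+/+ replicate 1, 4 of the 4 lists kept 56.9% or more of their median difference, which argues against that array as the sole cause, although the interferon list then missed the threshold (adjusted p = 0.0557, against 0.0024 to 0.208 over its alternatives at the preset correlation). Against 10000 random lists of matched mean signal, the lowest percentile among the oxidative phosphorylation, ribosomal protein and interferon lists was 99.6. This argues against brightness alone for these, while the mitotic list lay at 84.97 and may reflect such a shift. The random lists matched to the oxidative phosphorylation, ribosomal protein and interferon lists had medians of 0.06, 0.05 and 0.03. Brightness may thus make up part of each shift. Random genes were drawn independently, so the percentiles take no account of correlation among members. A difference in sex cannot be told apart from genotype and disease, since 0 groups held arrays of both kinds of sex-linked signal. The 4 arrays allow 3 splits, too few for a share under 0.05, and 1 of them, the real one, gave 4 lists, against at most 1 list in the others; for genes at least 2-fold different, 1 split of 3 gave the real 169, and the highest other was 112.

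For Snord92, the noise of single small RNA rows and transcription of its host gene were weighed. Within a group, 5 of the 278 tested small RNA genes differed between the arrays by as much as Snord92 did between groups, the largest by 5.18 log2 units. That sets single arrays against group means. Snord92 read 3.96 and 3.81 in Nol3+/+ and 8.26 and 7.74 in Nol3-/- MPN. Noise would thus have to move both arrays of a group alike. The comparison cannot decide on this, and noise of such rows stays open. The host gene Wdr43 differed by 0.52, with an upper bound of 1.13. The lower bound of the Snord92 difference was 2.61 when its dim Nol3+/+ signal was raised to the limit for dim genes. The Wdr43 row thus rose less than the Snord92 row. These rows have different probes and need not share a scale, so the bounds cannot exclude a higher host transcript as the whole cause. A part of the difference from the host also stays open, since the upper bound of Wdr43 lies above the 1 log2 unit set beforehand. A biological difference between the groups in this RNA stays open and untested.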

How the results depend on the processing

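Analyses without X- and Y-linked genes and of protein-coding genes only were chosen after seeing the data. The 4 genes past the adjusted limma threshold stayed called under each other variance model with moderation, array weights, normalization and limit for dim genes tried, and the mean of a gene's rows gave 6. With the replicate number as a block 0 genes passed, 197 were at least 2-fold different and 4 lists were called; the labels do not say that the numbers pair animals, and deviations of same-numbered arrays correlated at r = 0.0485 across genes. Leaving out 1 array gave 0 to 39 genes, 194 to 538 genes at least 2-fold different (without Nol3+/+ replicate 2 538, without Nol3-/- MPN replicate 2 310) and 1 to 5 lists. By construction the spread then comes from the complete group, and 680 genes differed 2-fold between the Nol3+/+ arrays against 347 between the Nol3-/- MPN arrays. The ordinary test without moderated variance gave 0 genes by adjusted p and 53 by the 2-fold criterion. A 1.5-fold limit gave 516 genes and an adjusted p threshold of 0.10 gave 5. Without X- and Y-linked genes 0 genes passed, with Snord92 and 4930539J05Rik at an adjusted p of 0.0648, 147 genes were at least 2-fold different and 4 lists were called. With protein-coding genes only the values were 1, 141 and 5. The count of lists went from 4 to 0 with an estimated correlation, with estimates between -0.02 and 0.03 and 2 residual degrees of freedom. It went to 0 with directional fry and to 1, the sex-linked list, with mixed fry. At the preset correlation the oxidative phosphorylation list was called under all 16 alternatives (adjusted p 3.7e-04 to 0.0476), the ribosomal list was lost only without Nol3-/- MPN replicate 1 (0.118, within 7.4e-04 to 0.118; median 0.23 against 0.19 over all arrays), and the mitotic list was lost with cyclic loess (0.0755, within 0.0056 to 0.208 over its alternatives; median 0.10, as in the main fit) and without Nol3+/+ replicate 2 or Nol3-/- MPN replicate 1 (0.190 and 0.208; medians 0.06 and 0.14). The causes of the other changes were not tested. Nol3 differed by -0.08 to 0.12, and its neighbourhood had odds ratios between 0.28 and 1.24, with none past the threshold. Over 109 genes and 12 settings other than leaving out an array, 1259 of 1266 values kept their side of the threshold, 6 lost and 1 gained a call, and 2 values of Ddx3x, near 0, changed sign. With an array left out, 5 of 436 gene values changed sign, over 3 genes. The leading higher and lower genes of the fixed rule had to show no overlap between the groups. Leaving out an array therefore cannot change their sign, and most of the other genes were picked for a small p. At most 4 of the 109 genes were called in the main fit, so few could lose a call. These gene counts are thus largely set by the choice of genes and do not measure robustness. List medians changed sign in 23 of 116 values, over 15 of 29 lists, with an array left out. In the other settings they did so in 9 of 375 values, over 6 lists. No called value changed sign. The median difference over all genes stayed between -0.02 and 0.03. Without detection values, how far signal over background limits dim genes is unknown.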

Other observations

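Both tests below were chosen after Irf8 and 4930539J05Rik had been seen, and their bounds were set before the tested values were seen. One hypothesis was that lower Irf8 may come with fewer cells primed towards dendritic cells and monocytes. A list of 25 dendritic cell and monocyte genes without Irf8 and H2-Aa was written first, of which 19 were measured and 4 are held by other lists. Its median log2 difference was -0.07, with 7 members higher and 12 lower (camera p = 0.195 at the preset correlation). Its brightest genes, Cst3, H2-Ab1 and Ctss, read 9.68, 8.07 and 7.73 in Nol3+/+ and 9.28, 7.84 and 7.56 in Nol3-/- MPN. The bound set for excluding the hypothesis was too weak, since a mean whose interval includes 0 also allows a small decrease, so the test decided neither way. The sort on Thy1+ LSK cells would remove mature cells of these types.

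A second hypothesis was that 4930539J05Rik on chromosome 3 may lie in a stretch of DNA of another strain that differs between the groups. Among the 50 nearest tested genes in the gene order of GRCm38.p6, 4 (8%) reached an unadjusted p under 0.05 against 5.79% of other genes. The odds ratio was 1.42 with an interval from 0.37 to 3.89 (two-sided Fisher's exact p = 0.535), which is too wide to tell.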
